A study of Rattus norvegicus with 2 samples.

How the data were processed

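The arrays measured messenger RNA of the NTS in 2 pooled samples, 1 from 5 male and 1 from 5 female Wistar Kyoto rats. Per the labels' protocols, the NTS was dissected from 1.0 mm rostral to 0.5 mm caudal of the calamus scriptorius, RNA had an integrity number above 7, and 150 ng of each pool was amplified and labelled with Cy3. The deposited intensity values come from single-colour Agilent arrays, per the file headers. The file headers name Agilent Feature Extraction version 10.7.3.1, whereas the submitters' processing notes give version 9.1. Per the file headers, the processed signal intensity is background-subtracted and detrended within each array, and no scaling between arrays had been applied. Both arrays lay on the same slide.

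A deposited value table of the series held a second form of the intensity values. Each of its columns equalled the processed signal times 1 factor per array, which set the 75th percentile to about 100, so the scale is linear and the values are not centred. The column medians were 28.0 for the male array and 27.3 for the female array. The table listed 37504 of 42877 rat spots, which were all spots without an outlier flag on either array and well above background on at least 1 array, with 0 exceptions.

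Each array held 30367 rat probes, 1390 of them spotted 10 times and 28977 spotted once. The log2 processed signal was set relative to the array's 75th percentile over rat spots, 3441 on the male array and 3380 on the female array, and the spots of a probe were averaged. Control spots and the 430 spots with an outlier flag on either array were left out. A probe was counted when it was well above background on both arrays, which left 24532 probes and 15567 genes, and a gene's value is the median of its counted probes. Counted probes of a gene differed by 4-fold or more in 1 of 2842 genes with several probes, Abcc12, at -1.41 and 0.74.

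Gene symbols came from the reference table of the GRCr8 assembly through the accession of the probe for 18758 probes and through another accession of the probe for 544. The symbol of the array files was kept for 3360 probes, and 7705 had no symbol. The 5775 counted probes without a symbol entered no count of genes: 14 of them were 2-fold or more higher in the female pool and 53 in the male pool. Symbols in the array files can be old. Chromosomes and positions are those of the array files, whose headers name the rn4 build, and no coordinate of the reference table was used.

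With 1 array per sex no test was possible, and genes were described by the size of the difference, with 2-fold as the threshold. A probe well above background on only 1 array gave a bound: its value minus the higher of the other array's lowest value among probes well above background and the probe's own value there. For each of 38 gene lists the median difference was set against 10000 random lists of the same size, drawn from 20 bins of brightness. The percentile describes these arrays and is not a test of sex, and under each alternative random lists were drawn anew. Scaling by the median, by spike-ins and the value table apply 1 factor per array, so they cannot move a list against random lists, and the other 9 alternatives were counted. Technical error was taken as the root mean square SD of the difference over the spots of repeated probes, which was 0.33 among the dimmest, then 0.15, 0.09 and 0.07. Within the male array the SD of such spots was 0.30, 0.14, 0.09 and 0.07 in these classes, and within the female array 0.22, 0.12, 0.08 and 0.07. The number of arrays limits the precision.

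The named genes were chosen by a rule: every measured Y-linked gene and Xist, the 12 largest differences in each direction among genes with a final symbol and at least a 2-fold difference, up to 4 members of each list with the largest difference, and the 5 largest bounds in each direction among genes with a final symbol. Xist was not analysed here. A few genes that the rule names are not reported here. The lists, the rule and the alternatives were fixed before the data were examined. The alternatives were scaling by the median, quantile normalization, scaling by the spike-ins with all spots well above background on both arrays, removal of the trend with brightness by a loess of span 0.3, normexp background correction with an offset of 50, the value table, 3 other filters on dim probes, flagged spots kept, the brightest probe of a gene, and thresholds of 1.5-fold and 3-fold. Leaving out 4 of 20 bands of array rows was added after seeing the data; these are the bands where the share of dim spots 2-fold or more brighter on the male array was over 3 times that of the median band.

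The steps were tested on simulated data, with spot noise as measured and 200 genes changed among 15671. For this comparison all 66 genes changed 4-fold were called at 2-fold, with a mean of 2.02 recovered, and 3 of 15471 unchanged genes were called. The simulated noise was normal, and both arrays shared the same background and outlier flags. It held no outlying spots, crowded bands or error between labelling reactions, so the 3 calls give no rate of false calls for the real arrays. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, and in R 4.3.3 with limma 3.58.1.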

Results

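Gene expression was measured in the nucleus tractus solitarius (NTS) of adult Wistar Kyoto rats, a normotensive laboratory strain. The NTS is the brainstem nucleus that receives the first central input from baroreceptors and other visceral afferents. Total RNA from 5 males and 5 females, all 9 weeks old, was pooled by sex, with 100 ng per rat, and each pool was hybridised to 1 single-colour array. Every value below is therefore a difference between 2 arrays, given as female minus male on the log2 scale. The design has 1 array per sex, so no difference has a replicate check and no test was made. The spread of repeated spots stands for technical error within an array and leaves out the differences between rats and between labelling reactions. Of 42877 rat spots, 85.5% were well above background on the male array and 87.9% on the female array, and no spot was saturated.

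The first comparison asked whether the sex labels could be checked. The Y-linked list held 1 measured gene, Sry, the testis-determining factor. Its probe gave a processed signal of 79.8 on the male array and 75.1 on the female array, a difference of -0.062 against a spot SD of 0.15 at that brightness. Y-linked genes are carried by males only, so with correct labels the signal on the female array cannot come from Sry. The equal male signal is then no sign of Sry either. A second Y-linked probe, for Tspy1, was not well above background on either array. A probe that the array files name Ddx3y carries an accession that the reference table assigns to the gene Ddx3, and it gave 0.21. These probes do not separate the pools. X-linked genes with reported escape from X inactivation gave the other check: 8 of 9 measured members were higher in the female pool, with a median of 0.20. That median lay at percentile 100 of 10000 random lists matched on brightness. Eif2s3, a translation initiation factor subunit, differed by 0.65, the histone demethylase Kdm5c by 0.57, Pbdc1 by 0.50 and the RNA helicase Ddx3x by 0.39, each against a spot SD of 0.07. The other 499 X-linked genes had a median of -0.019. Single-spot probes of Eif2s3, Kdm5c and Pbdc1 lay in 4 bands of array rows that hold many dim outlying spots, and the list median was 0.11 without those bands.

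The main comparison asked which genes of the NTS differ between male and female rats. Of all genes, 17 were 2-fold or more higher in the female pool against 65 in the male pool, out of 15567 genes with a counted probe. This direction depended on the filter. With probes well above background on at least 1 array the counts were 212 and 157, and without a background filter 438 and 275. The probes that these filters add were not well above background on 1 or both arrays, and the floors of the arrays differed. Genes well above background on 1 array only, when bounded by the floors, gave 30 at 2-fold or more on the female array and 63 on the male array. Of the 82 genes, 80 rest on 1 probe and 1 spot, among them every gene named in this and the next paragraph. The largest female excess among genes with a final symbol was 1.81 for S100g, a small calcium-binding protein, followed by Tpd52l3 at 1.58 and the odorant receptor gene Or6k8 at 1.56. RGD1563270, whose symbol is provisional, had a larger female excess of 3.16, an 8.91-fold difference. E-cadherin, Cdh1, was higher in the female pool by 1.52. The largest male excess was in Cd86, a costimulatory ligand of antigen-presenting cells, at -3.28, a 9.69-fold difference. It was followed by the odorant receptor gene Or4f15 at -2.96 and Tulp1, a gene known from photoreceptors, at -2.58.

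Further genes with a female excess were Elfn1 at 1.41, Dnase1l3 at 1.27, 4933405O20Rikl at 1.18, Ddit4l2 and Ranbp17 at 1.17 each, and the mast cell protease gene Mcpt9 at 1.17. Nacad followed at 1.14, and Qrfp, which encodes a neuropeptide, at 1.07. On the male side Lmntd1 differed by -2.34 and the vomeronasal receptor genes Vom1r23 and Vom1r98 by -2.25 and -1.90. The neutrophil granule protein gene Ltf differed by -2.14 and Cldn2, a tight junction gene of choroid plexus epithelium, by -1.84. Il17re gave -1.82, Tnfrsf13c, the receptor for a B cell survival factor, -1.81, Esyt3 -1.77 and C14h1orf146 -1.75. By the array files' coordinates on the rat genome build rn4, the S100g probe lies on chromosome X from 52449257 to 52449316. The Cd86 probe lies on chromosome 11 from 66228898 to 66228957, and the Cdh1 probe on chromosome 19 from 36511853 to 36511912.

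**Figure D1:**
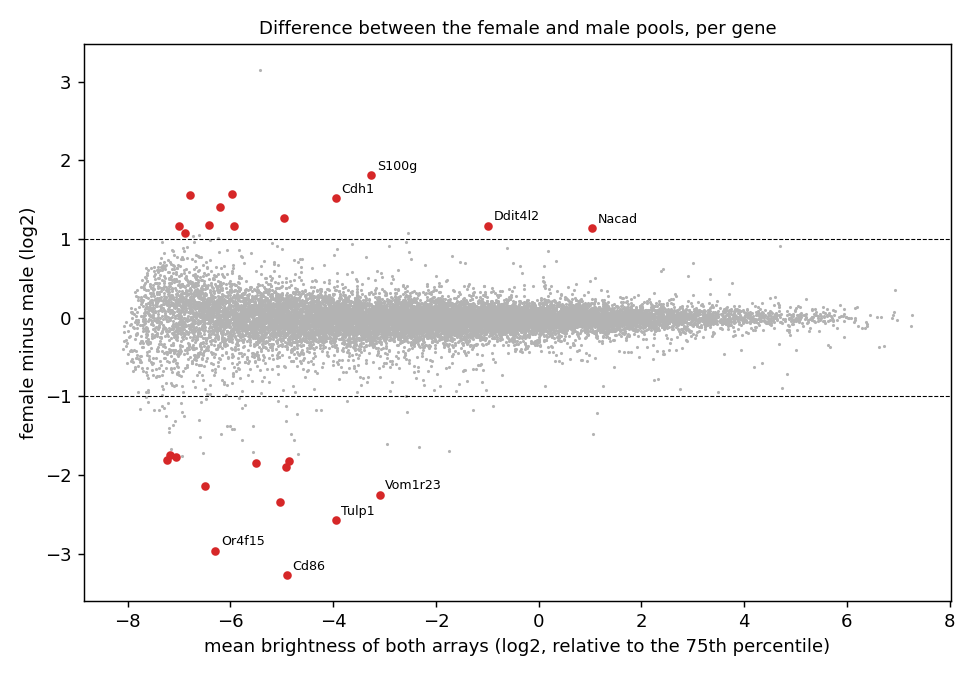
Each point is 1 gene, with the mean brightness of both arrays on the horizontal axis (log2, relative to the 75th percentile) and the female minus male difference on the vertical axis (log2). Dashed lines mark a 2-fold difference, and the spread is widest among dim genes. Red points are, among genes with a final symbol, the 12 with the largest difference in each direction.

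Most of these differences were in dim genes. Of the 65 genes with a male excess, 31 were over 64-fold below the 75th percentile, where the spot SD of the difference was 0.33, and 22 more were 16- to 64-fold below it, where the SD was 0.15. In the brightest class, where the SD was 0.07, there were 2 genes with a female excess, Ddit4l2 and Nacad, and 5 with a male excess. Those 5 were Ctsk, a collagen-degrading protease of osteoclasts and fibroblasts, at -1.70, Olfml3 at -1.47, the cobalamin carrier gene Tcn2 at -1.22, Chdh at -1.17 and Zfp772 at -1.13. Spp1, osteopontin, was measured with 10 spots and differed by -1.64. The genes named for their brightness class, Spp1 and RGD1563270 were chosen after their values were seen. Normexp background correction left 5 and 18 of the 17 and 65 genes at 2-fold or more. All differences are relative to the 75th percentile of each array; scaling by the spike-in probes instead shifts every gene by 0.68 towards the female pool and gives 611 and 17 genes. Of the 65 genes with a male excess, 31 had a single-spot probe in the 4 bands noted above, which hold 20.4% of the rat spots and were picked for their male-bright dim spots, among them Cd86, Or4f15, Vom1r98, Tnfrsf13c, Esyt3, C14h1orf146, Ctsk and Olfml3. Of the 17 genes with a female excess, 6 had one there, among them Or6k8, Elfn1, 4933405O20Rikl and Ranbp17. Of 150 entries for Sry and for list members picked out by their difference, 37 had one, among them Lbp, Gper1, Edn3, Vip, Prkg1 and Slc6a4. A gene has 1 entry for each list or rule that names it.

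Some genes were well above background on 1 array and on no probe of the other. There were 608 such genes on the female array and 97 on the male array. The difference was at least 2-fold for 30 and 63 of them. The lowest processed signal well above background was 13.1 on the male array and 9.59 on the female array. On the scaled log2 values, bounds for the female array were set against a floor of -8.03, and those for the male array against -8.46. With these unequal floors, the counts cannot be read as a difference between the sexes. Among genes with a final symbol, the largest bounds on the female array were at least 7.82-fold for Tnni1, a troponin of slow muscle, 5.84-fold for Mnda and 4.95-fold for the odorant receptor gene Or10g1. Acer1 had a bound of at least 3.43-fold. On the male array the odorant receptor gene Or4k1 was at least 16.5-fold higher, Wasfl 12.004-fold, Topaz1 7.17-fold, Prl2a1 7.04-fold and Sult1c2a 7.03-fold. Each of these bounds rests on 1 spot.

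Relative to the 75th percentile, genes of blood cells, meninges and choroid plexus were higher in the male pool. All 8 measured red blood cell genes were higher there, with a median of -0.46, and so were 10 of 12 white blood cell genes, with a median of -0.40. In 17 of 18 genes of meninges and fibroblasts the male pool was higher, with a median of -0.28. These 3 medians lay at percentile 0.0 of random lists. The choroid plexus list, with 16 of 21 members higher in the male pool, had a median of -0.13 at percentile 0.37. Outside the 4 bands and among the brighter probes, meninges gave -0.30 and red cells -0.40, both at percentile 0.0, whereas choroid plexus gave -0.057 at percentile 22.6 over 4 genes and white cells -0.092 at percentile 8.53 over 2, both inside the range of 95% of random lists. With spike-in scaling the medians of the 4 full lists turned to the female side, at 0.22 for red cells, 0.28 for white cells, 0.40 for meninges and 0.55 for choroid plexus.

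Among red cell genes the anion exchanger Slc4a1 differed by -0.85, the haemoglobin chaperone Ahsp by -0.81 and the haem synthesis enzyme Alas2 by -0.51. The white cell genes with the largest differences encode neutrophil granule and cytosol proteins: S100a8 at -0.76, Np4 at -0.76, Mpo at -0.65 and S100a9 at -0.58. Mpo was dim, with a spot SD of 0.33. S100a8, Np4 and Mpo have their probe in the 4 bands, and the white cell median was -0.22 without them. In the meninges list the collagen gene Col1a2 differed by -0.90, the retinoic acid synthesis gene Aldh1a2 by -0.54, Igfbp2 by -0.43 and Slc47a1 by -0.42. In the choroid plexus list Lbp differed by -0.91 and the water channel gene Aqp1 by -0.61 over 10 spots. The transcription factor gene Otx2 differed by -0.37, while the dim Tmem72 gave 0.38.

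Glial lists moved by smaller amounts and in both directions. Oligodendrocyte genes were higher in the female pool in 10 of 14 cases, with a median of 0.073 at percentile 99.5, led by the myelin genes Mog at 0.47, Mobp at 0.36, Mag at 0.27 and Mal at 0.27. Oligodendrocyte precursor genes had a median of 0.097 at percentile 99.8, with Olig1 at 0.28, Pdgfra at 0.18, Ptprz1 at 0.18 and Sox10 at 0.14. Astrocyte genes were higher in the male pool in 9 of 14 cases, with a median of -0.070 at percentile 1.68. The intermediate filament gene Gfap differed by -0.32 over 10 spots, the water channel Aqp4 by -0.26 and the glutamate transporter Slc1a3 by -0.15, against 0.21 for Gjb6. The 3 probes of Aqp4 ran from -0.32 to 0.017, and the 2 probes of Slc1a3 gave -0.26 and -0.038. The astrocyte median was inside the random range under 3 of 9 alternatives: -0.024 with quantile normalization, -0.022 with the brightest probe of each gene and -0.054 with normexp. Microglia and macrophage genes had a median of -0.081 at percentile 2.05, with Cd68 at -0.63, Csf1r at -0.28, C1qc at -0.22 and Aif1 at -0.16, and this median was inside the range under 6 of 9 alternatives. Endothelial genes had a median of 0.071 at percentile 97.7, led by the glucose transporter Slc2a1 at 0.26, Abcb1a at 0.25, Cldn5 at 0.21 and Esam at 0.19. Abcb1a was dim and lay within its spot SD of 0.33. The endothelial median was inside the range under 5 of 9 alternatives, with 0.024 under normexp.

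The neuron list had a median of 0.0031 over 13 genes at percentile 65.9, with 7 members higher in the female pool and 6 in the male pool. Snap25, of the synaptic vesicle fusion machinery, differed by 0.24, Nefl by -0.16, Nefm by -0.086 and Eno2 by -0.052. The 2 probes of Eno2 disagreed, at -0.23 and 0.12. Pericyte and smooth muscle genes had a median of -0.018, with Mylk at -0.46, Myh11 at -0.32, Tpm2 at 0.18 and Myl9 at -0.13. Ependyma and cilia genes had a median of -0.066 at percentile 10.02, with Spa17 at 0.88, Hydin at -0.34, Mlf1 at -0.25 and Rarres2 at -0.19. The lists for cerebellum, motor nuclei, area postrema and hindbrain level were inside the range of 95% of random lists under every alternative. The cerebellum list had a median of -0.0081, with Zic1 at -0.48, Pcp2 at -0.41, the dim Fat2 at 0.35 over 8 spots and Barhl1 at 0.34. Motor and cholinergic neuron genes had a median of -0.068, with Tbx20 at -0.49, Tbx3 at -0.27, Chodl at 0.22 and Slc18a3 at -0.15. Tbx20 and Chodl were dim, with a spot SD of 0.33, and Chodl lay within 1 of these SDs. The area postrema list had a median of 0.032, with Calcr at 0.24, Ramp3 at -0.15 and Cckar at -0.15. Hox and dorsal hindbrain factors, which mark the rostrocaudal level, had a median of 0.035, with Hoxa7 at 0.36, Hoxc6 at 0.31, Hoxb6 at 0.24 and Lmx1b at 0.23.

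**Figure D2:**
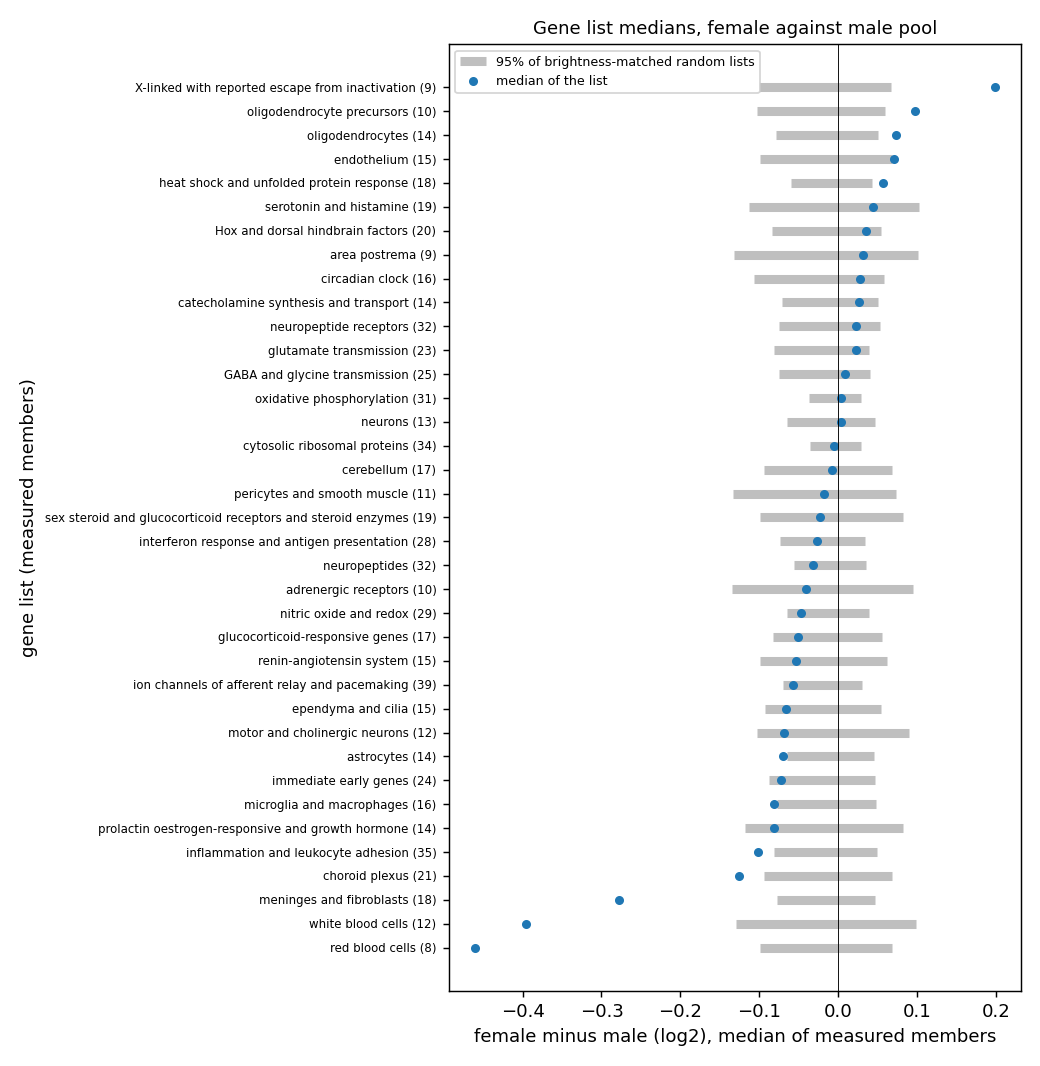
Each dot is the median female minus male difference (log2) of the measured members of 1 gene list, with their number in brackets, and each grey bar spans 95% of 10000 random lists of the same size matched on brightness. Red blood cells, white blood cells, and meninges and fibroblasts lie farthest to the male side at -0.46, -0.40 and -0.28, and X-linked genes with reported escape lie farthest to the female side at 0.20.

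Genes of hormone action were compared next. The list of sex steroid and glucocorticoid receptors and steroid enzymes had a median of -0.023 over 19 genes, at percentile 38.9. The progesterone receptor gene Pgr was higher in the female pool by 0.63, the oestrogen receptor beta gene Esr2 by 0.50 and the mineralocorticoid receptor gene Nr3c2 by 0.44, whose 2 probes disagreed at 0.013 and 0.87. The membrane oestrogen receptor gene Gper1 was higher in the male pool, at -0.55. Pgr and Esr2 were dim, with a spot SD of 0.15 and 0.33. The list of prolactin, growth hormone and their responsive genes had a median of -0.081 at percentile 9.75, with Gh1 at 0.67, Stat5b at -0.36 and Socs2 at -0.30.

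Cardiovascular and transmitter lists had medians inside the range of random lists, although some left it under an alternative. The renin-angiotensin list had a median of -0.054 over 15 genes at percentile 18.2, and -0.15, outside the range, without a background filter. Its largest difference was in Mas1, the receptor for angiotensin-(1-7), at -1.001, followed by Enpep at -0.34, Lnpep at -0.27 and Prcp at 0.23. Catecholamine synthesis and transport genes had a median of 0.026, with Maob at -0.45, Gch1 at -0.22 and Qdpr at 0.15. Adrenergic receptors had a median of -0.040, with Adra2a at 0.25, Adrb3 at -0.24, Adra1a at -0.17 and Adra2b at 0.12. Adrb3 was dim and lay within its spot SD of 0.33.

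Glutamate transmission genes had a median of 0.023, which was above the range under 4 of 9 alternatives, from 0.054 to 0.059, while the receptor subunit genes Grin2a, Gria1, Grin2d and Grin2b differed by -0.41, -0.34, -0.34 and -0.30. GABA and glycine transmission genes had a median of 0.0082, and 0.11, above the range, among probes brighter than the median probe. The bright gene of the metabotropic GABA receptor subunit Gabbr2 was higher in the female pool by 0.69 against a spot SD of 0.07, and the vesicular transporter gene Slc32a1 by 0.30, whereas Gabrg1 gave -0.30 and the dim Gabre -0.69. Neuropeptide genes had a median of -0.032 over 32 genes. Prlh, the prolactin-releasing peptide of NTS noradrenergic neurons, was higher in the female pool by 0.62, and Edn3 was higher in the male pool, at -0.66. The dim genes Vip and Edn1 gave -0.72 and 0.38. Neuropeptide receptors had a median of 0.023, with Oprd1 at 0.46, Cckbr at 0.41, Npr1 at -0.37 and Mc3r at 0.27. Mc3r was dim and lay within its spot SD of 0.33. With the brightest probe of each gene the median of the list was 0.084, above the range. Serotonin and histamine genes had a median of 0.044, with Slc6a4 at 0.74, Htr2c at 0.67, Htr4 at 0.30 and Htr6 at 0.26. Slc6a4 and Htr4 were dim, with a spot SD of 0.33, and Htr4 lay within 1 of these SDs. The median of the list was above the range at 0.14 among the brighter probes and at 0.16 without the 4 bands. Ion channels of afferent relay and pacemaking had a median of -0.057 over 39 genes, with the pacemaker channel gene Hcn4 at -0.64, Kcna1 at 0.40 and P2rx4 at -0.34. The sign of this median did not hold, at 0.0080 among the brighter probes and 0.0025 with the brightest probe of each gene.

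Of the inflammatory lists, inflammation and leukocyte adhesion stood apart. Of its 35 measured genes 25 were higher in the male pool, with a median of -0.10 at percentile 0.53, which became -0.063 at percentile 13.1 among probes brighter than the median probe. The chemokine gene Cxcl10 differed by -1.48, the adhesion gene Selp by -1.08, Nfkbiz by -0.65 and Lcn2, a neutrophil and acute phase protein gene, by -0.63. Cxcl10, Selp and Nfkbiz were dim, with a spot SD of 0.33, and Nfkbiz lay within 2 of these SDs. Interferon response and antigen presentation genes had a median of -0.027 at percentile 39.9, with Rsad2 at -0.66, Ifit3 at -0.29, Isg15 at 0.27 and Mx1 at 0.21. Nitric oxide and redox genes had a median of -0.047, with Cybb at 0.87, Prkg1 at -0.73, Nos2 at 0.39 and Prdx6 at -0.26. The median was -0.071, below the range, among the brighter probes. Cybb and Prkg1 were dim, with a spot SD of 0.33. Blood cell genes, given above, also lay on the male side, and a link between them and the inflammation list was not tested.

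Stress and activity lists moved little. Heat shock and unfolded protein response genes were higher in the female pool in 15 of 18 cases, with a median of 0.057 at percentile 99.4. Hsph1 differed by 0.35 and Hspa1b by 0.28 over 10 spots, against -0.23 for Hspb1 and -0.22 for Pdia4. Immediate early genes had a median of -0.072 at percentile 6.31, with Egr3 at 0.49, Fosl2 at -0.43, Egr1 at -0.38 and Nr4a1 at -0.34 over 10 spots. Egr3 and Fosl2 were dim, with a spot SD of 0.33. Glucocorticoid-responsive genes had a median of -0.051, with the dim Pdk4 at -0.51, Per1 at -0.40 and Zbtb16 at 0.32. With normexp their median was -0.076, below the range. Circadian clock genes had a median of 0.028, with Bhlhe40 at 0.27, Npas2 at 0.23 and Clock at -0.19, and a median of 0.11, above the range, among the brighter probes. Oxidative phosphorylation genes had a median of 0.0036, with Ndufa4 at 0.44, Uqcrc1 at 0.28, Atp5f1b at -0.18 and Cox5a at -0.15. Cytosolic ribosomal protein genes had a median of -0.0051, with Rpl27 at -0.17, Rps9 at -0.15, Rps4x at -0.096 and Rps15 at 0.076. In all, 12 of 38 lists lay outside the range of 95% of random lists, 7 on the male side and 5 on the female side. Lists share members, and markers of 1 cell type move together, so this number is not set against chance. Of these 12, 6 stayed outside under each of the 9 alternatives that can move a list against random lists: X-linked genes with reported escape, red blood cells, meninges and fibroblasts, oligodendrocytes, their precursors, and heat shock and unfolded protein response. Of the 26 lists inside the range, 8 lay outside it under at least 1 of these alternatives, and 9 had the other sign under at least 1.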

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

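The tests on the spike-in transcripts were chosen after their difference was seen. The spike-in probes, which lie outside every comparison of the report, were dimmer on the female array: the 7 of 10 spike-ins with all 32 spots well above background on both arrays had a mean difference of -0.68 after scaling, from -0.79 to -0.60. The other 3, with only part of their spots above background, gave -0.45, -0.29 and 0.36 and were left out of the mean. A dimmer female array as a whole is argued against, because the 75th percentiles of the rat spots differed by -0.026 on the log2 scale. The SD of the 7 differences was 0.064, which a larger amount of spike-in RNA in the male labelling and a larger amount of messenger RNA per total RNA in the female pool would both give, so these cannot be told apart. A difference between the sexes in messenger RNA content is therefore open and untested.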

How the results depend on the processing

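Leaving out the 4 bands of array rows was chosen after seeing the data, and the other alternatives before. No paired analysis was possible because there is 1 array per sex, and no array could be left out. The 17 and 65 genes with a female and male excess became 611 and 17 with spike-in scaling, which shifts every gene by 0.68. They became 5 and 18 with normexp, 212 and 157 with probes well above background on at least 1 array, 438 and 275 without a background filter, and 2 and 8 among probes brighter than the median probe. The larger count was thus on the female side with spike-in scaling, with the looser filter and without a filter. The probes added by the looser filter and without a filter were not well above background on 1 or both arrays, whose floors differed. A threshold of 1.5-fold gave 141 and 245 genes and 3-fold gave 2 and 20. Without the 4 bands there were 12 and 36. The female count was 16 to 21 and the male count 61 to 71 under the other alternatives. With each array's median the lists moved to 0.061 for catecholamine synthesis and transport, 0.058 for glutamate transmission, 0.043 for GABA and glycine transmission, 0.0032 for neuropeptides, 0.058 for neuropeptide receptors, -0.012 for nitric oxide and redox, -0.067 for inflammation and leukocyte adhesion, 0.0078 for interferon response and antigen presentation, -0.022 for ion channels of afferent relay and pacemaking, -0.038 for immediate early genes, 0.092 for heat shock and unfolded protein response, 0.038 for oxidative phosphorylation, 0.029 for cytosolic ribosomal proteins, 0.038 for neurons, -0.035 for astrocytes, 0.11 for oligodendrocytes, -0.046 for microglia and macrophages and -0.24 for meninges and fibroblasts. With spike-in scaling every list lay on the female side: 0.62 for Y-linked, 0.88 for X-linked with reported escape from inactivation, 0.65 for sex steroid and glucocorticoid receptors and steroid enzymes, 0.60 for prolactin oestrogen-responsive and growth hormone, 0.62 for renin-angiotensin system, 0.70 for catecholamine synthesis and transport, 0.64 for adrenergic receptors, 0.70 for glutamate transmission, 0.69 for GABA and glycine transmission, 0.65 for neuropeptides, 0.70 for neuropeptide receptors, 0.72 for serotonin and histamine, 0.63 for nitric oxide and redox, 0.58 for inflammation and leukocyte adhesion, 0.65 for interferon response and antigen presentation, 0.62 for ion channels of afferent relay and pacemaking, 0.61 for immediate early genes, 0.63 for glucocorticoid-responsive genes, 0.73 for heat shock and unfolded protein response, 0.71 for circadian clock, 0.68 for oxidative phosphorylation, 0.67 for cytosolic ribosomal proteins, 0.68 for neurons, 0.61 for astrocytes, 0.75 for oligodendrocytes, 0.78 for oligodendrocyte precursors, 0.60 for microglia and macrophages, 0.75 for endothelium, 0.66 for pericytes and smooth muscle, 0.40 for meninges and fibroblasts, 0.55 for choroid plexus, 0.61 for ependyma and cilia, 0.22 for red blood cells, 0.28 for white blood cells, 0.67 for cerebellum, 0.61 for motor and cholinergic neurons, 0.71 for area postrema and 0.71 for Hox and dorsal hindbrain factors. With quantile normalization the lists gave 0.059 for glutamate transmission and -0.024 for astrocytes. With normexp the lists gave -0.011 for glutamate transmission, -0.044 for microglia and macrophages, 0.024 for endothelium, -0.23 for white blood cells and -0.036 for area postrema. Without a background filter the lists gave -0.021 for prolactin oestrogen-responsive and growth hormone, -0.15 for renin-angiotensin system, 0.043 for pericytes and smooth muscle, -0.41 for red blood cells, -0.28 for white blood cells and -0.0013 for Hox and dorsal hindbrain factors. With only probes brighter than the median probe the lists gave 0.30 for X-linked with reported escape from inactivation, 0.057 for glutamate transmission, 0.11 for GABA and glycine transmission, 0.059 for neuropeptide receptors, 0.14 for serotonin and histamine, -0.063 for inflammation and leukocyte adhesion, 0.0080 for ion channels of afferent relay and pacemaking, 0.11 for circadian clock, 0.14 for endothelium, -0.13 for pericytes and smooth muscle, -0.38 for red blood cells, -0.092 for white blood cells, -0.081 for cerebellum and -0.013 for Hox and dorsal hindbrain factors. With the brightest probe of each gene the lists gave 0.29 for X-linked with reported escape from inactivation, 0.054 for glutamate transmission, 0.084 for neuropeptide receptors, 0.0025 for ion channels of afferent relay and pacemaking and -0.022 for astrocytes. With probes well above background on at least 1 array the lists gave -0.41 for red blood cells. Without the 4 bands the lists gave 0.11 for X-linked with reported escape from inactivation, 0.054 for glutamate transmission, 0.16 for serotonin and histamine, -0.24 for meninges and fibroblasts, -0.22 for white blood cells and -0.054 for area postrema. Scaling by the median shifted every list alike by 0.035, and scaling by the spike-ins by 0.68, each through 1 factor per array. The lists given for the median are those where 0.035 exceeded the SD of the random lists' medians. Normexp compresses dim differences by its offset and a stricter filter leaves fewer genes. For the remaining shifts the cause was not tested. The 7 lists outside the random range on the male side reversed with spike-in scaling, and the 12 lists kept their sign under the other alternatives. Under all 9 alternatives that can move a list against random lists 6 lists stayed outside. Microglia and macrophages were inside under 6, endothelium under 5, astrocytes under 3, and choroid plexus, white blood cells and inflammation under 1 each. Of the values of named genes under the alternatives, 1509 moved by no more than the spot SD and 259 by more, 169 of these with spike-in scaling and 65 with normexp. Part of this tally was fixed in advance. The value table and scaling by the median, which shifts genes by 0.035, left 169 values each within the spot SD. The shift of 0.68 with spike-in scaling exceeds the largest spot SD, 0.33. Signal over background limits the dim genes.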

Other observations

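The tests on the bright members of the meninges and choroid plexus lists, and the shuffles of dim spots, were chosen after their values were seen. Blood, meninges and choroid plexus genes were higher in the male pool relative to the 75th percentile. Hba-a1, Hbb and Alas2 differed by -0.25, -0.41 and -0.51, but they belong to the red cell list, so more residual blood in the male pool cannot be told apart from another cause. Local signal on the male array is argued against for meninges, whose median was -0.30 at percentile 0.0 outside the 4 bands and among the brighter probes, whereas there choroid plexus gave -0.057 at percentile 22.6 over 4 genes and white cells -0.092 at percentile 8.53 over 2. For more meninges or choroid plexus tissue in the male pool, the bright members with the smallest male excess, Igf2 at -0.12 and Enpp2 at -0.081, lay within 2 spot SDs, 0.14, so these cannot be told apart from a difference between the sexes, which is open and untested.

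Dim probes with a male excess crowded in 4 of 20 bands of array rows, which are the bands with over 3 times the share of the median band, 1.19%. In them 7.05% of dim spots were 2-fold or more brighter on the male array, against 1.09% in the other bands, a contrast that the choice of bands widens. Dim spots 2-fold or more brighter on the female array made up 4.30% in these bands and 3.53% in the other bands, from 1.62% to 6.76% by band. A rise of the surface signal across these bands is argued against: negative control spots in these bands differed by -1.67 raw units, within the SD of 2.39 around the mean of -1.28 in the other bands. That SD is the spread of single bands. With 6 to 9 control spots in each of the 4 bands, a rise at scattered places could be missed. Genes that are higher in males are argued against as the cause of the crowding: the highest band held 11.3%, above the highest of 1000 shuffles of the dim spots over the bands, 5.44%, while probes of the same gene shared a band in 5.17% of 3248 pairs, within 2 SDs, with an SD of 0.386, of the 5.02% expected by chance. This leaves open whether any single gene there is higher in males. Spots 2-fold or more below their own probe made up 3.46% inside the bands, 15 of 433, and 1.98% outside, 33 of 1665. These counts are too few to decide whether scattered spots with extra signal on the male array cause the crowding, and its cause stays open.

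The median of the 499 X-linked genes outside the escape list was -0.019, below the 0.20 of the escape list.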
